A study of Mus musculus with 8 samples.

How the data were processed

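Total RNA from the epidermis of newborn C57BL/6J mice (postnatal day 0) was profiled on 8 expression arrays, 1 per sample. Per the labels, RNA was extracted with a Maxwell 16 LEV simplyRNA kit, amplified with the NuGEN Applause WT-Amp Plus ST system and labelled with biotin. The group of each array was taken from its genotype label. In 4 arrays K320E-Twinkle, a mutant of the helicase that unwinds mitochondrial DNA, was expressed in the epidermis through the K14 promoter. The other 4 came from control newborns whose genotype label is R26-K320E-Twinkle loxP/+. That label names K320E-Twinkle too, so the contrast is not one of carriers against non-carriers. The labels do not state that the arrays come from separate animals or litters, so p-values measure only the spread between these samples, which may be technical.

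The values deposited by the authors are log2 intensities of 33793 probe sets. They range from about 4.31 to 13.1, and the medians of the 8 arrays lie between 6.06 and 6.11. The background correction, summarisation and normalisation behind them are not given in the sources used here, and the values were used as they stand. No pair of arrays held identical values. The number of arrays, 4 per group, limits the precision.

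Probe sets were named through the platform annotation held by GEO, with a gene table of assembly GRCm38.p6 used for names only. A single gene symbol was given for 23521 probe sets, several symbols for 1814, and 8458 were unnamed here. The probe set with the highest mean over all 8 arrays represented each gene, which left 22180 genes, 1082 of them with more than 1 probe set. Of the called genes, 12 had more than 1 probe set, and in 1 of these the probe sets had opposite signs.

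The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, genotype as the only term, all 8 arrays). P-values were adjusted over all genes with the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are K320E minus control on the log2 scale, with the moderated SE. The mean levels of Twnk and of the respiratory chain lists were compared with exact two-sided permutation tests of 4 arrays against 4, for which the smallest possible p is 0.0286.

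Before the data were examined, 46 gene lists with 837 entries were fixed: 31 theme lists, 14 lists of markers of other cell types, and a Y-linked list used as a measure of sex. Of the entries, 763 matched a measured gene, 34 of them through an older name, and 37 fell on probe sets of several genes and were left out. The 45 theme and cell type lists were tested with limma's camera (two-sided, preset inter-gene correlation of 0.01, adjusted over the 45 lists). Camera compares a list with all other genes. With a correlation estimated per list, 1 of the 23 called lists, the integrated stress response list, stayed past the threshold. Over the other called lists the adjusted p with an estimated correlation ran from 0.0936 to 0.546, and for 15 of the 23 called lists it was the highest over all alternatives tried. Counts of genes within a list are given over all genes and also adjusted over the list alone.

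The rule for naming genes was also fixed before the data were examined. It takes Twnk and the 8 highest and the 8 lowest fold changes among called genes whose groups do not overlap. Gm, LOC and Rik names and genes of small non-coding RNAs are left out of these, while pseudogenes are kept. From each called theme list it takes up to 3 called members, and from each other theme list 1. From each cell type list it takes the 2 most highly expressed members. Other members of the fixed lists that the text names, and genes outside the lists, were chosen after their values were seen.

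The scripts were tested on simulated data for the K320E against control comparison, with 200 of 22180 genes changed. The fit recovered 83.6% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, with 10 false calls. It called 0 genes when no change was simulated. Noise was drawn for each gene on its own, with no spread shared within an array, so recovery may be lower in the real arrays. All 3 lists shifted by 0.5 log2 units were called and 0 others, in a simulation without correlation between genes.

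The alternatives were quantile normalisation, median centring, the mean over probe sets, every probe set tested, a filter that left out the lowest 33.3% of genes by mean level, an intensity trend with a robust prior, array quality weights, the replicate number as a block, a covariate for the Y-linked level, a minimum fold of 1.5, camera with an estimated correlation, fry, and leaving out each array in turn. Leaving out control replicates 2 and 3 together and a covariate for the hair structure list were added after the data were seen.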

Results

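The data compare epidermal transcripts at birth between mice that express a mutant mitochondrial helicase in the epidermis and controls. Twinkle, encoded by Twnk, unwinds mitochondrial DNA (mtDNA) at the replication fork. Log2 intensities were compared between 4 K320E-TwinkleEpi arrays (K320E below) and 4 arrays of control newborns. Correlations between arrays ran from 0.987 to 0.994 within the groups and from 0.976 to 0.993 between them. The first principal component held 39.8% of the variance, and all 4 K320E arrays lay on 1 side of it and all 4 controls on the other. The sex-linked transcripts of 2 control arrays were unusual: Xist was at 6.17 in control replicate 3, with a Y-linked mean of 4.75, and at 9.27 in control replicate 2, with a Y-linked mean of 9.05.

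Twnk itself was higher in every K320E array than in every control. Its probe set (17359787) measured 9.05 ± 0.18 in K320E and 6.73 ± 0.18 in controls (SD, n = 4 each), a log2 fold change of 2.31 (SE 0.11; limma adjusted p = 0.00011) or 4.97-fold. The exact permutation test of the 4 against 4 arrays gave p = 0.0286, the smallest it allows. The Twnk level matched the genotype label on all 8 arrays; the probe set does not tell the mutant transcript from the normal one.

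The series title names an imbalance of respiratory chain complexes, and the transcripts of their subunits were compared by the genome that encodes them. Of the 13 mtDNA-encoded subunits fixed, mt-Co2, mt-Atp6 and mt-Atp8 lay on probe sets of several genes and were left out. No mtDNA-encoded subunit of complex V was therefore measured. Of the 10 mtDNA-encoded subunits measured, 9 fell in K320E over all genes and 10 when adjusted over the list alone (limma). The largest decreases were in complex I subunits: mt-Nd3 fell by 1.04 (SE 0.10, adjusted p = 0.0037), mt-Nd4l by 0.84 (SE 0.11, adjusted p = 0.014) and mt-Nd2 by 0.64 (SE 0.06, adjusted p = 0.0043) on the log2 scale in limma's fit. The complex III subunit mt-Cytb fell by 0.49 and the complex IV subunit mt-Co3 by 0.56, while mt-Co1 had a log2 fold change of -0.33 and an adjusted p of 0.059. mt-Nd6, the subunit encoded on the light strand, fell by 0.43. The list had a median of -0.48 (camera adjusted p = 1.57e-20; adjusted p = 0.094 with an estimated correlation).

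The nuclear-encoded subunits did not show this shift. Their mean over complexes I, III, IV and V was 9.34 ± 0.04 in K320E and 9.36 ± 0.04 in controls (SD, n = 4 each), a difference of -0.017 (exact permutation p = 0.514). The mean of the mtDNA-encoded list was 11.81 ± 0.06 against 12.37 ± 0.07 (SD, n = 4 each). Its exact permutation p was 0.0286, or 0.080 adjusted over the 45 lists. Within each array, the mtDNA-encoded mean minus the nuclear-encoded mean was 2.47 ± 0.06 in K320E and 3.01 ± 0.06 in controls. This difference of -0.54 (SE 0.04, n = 4 each) had an exact permutation p of 0.0286. The means do not cover the same complexes, since the mtDNA-encoded one holds no complex V subunit and is mostly complex I. Camera called no shift for nuclear-encoded complex I (32 genes, median -0.02, adjusted p = 0.336), complex II (4 genes, median 0.12, adjusted p = 0.516), complex III (8 genes, median 0.03, adjusted p = 0.655), complex IV (11 genes, median -0.06, adjusted p = 0.336) or complex V (16 genes, median -0.03, adjusted p = 0.297). In these 5 lists 1 gene changed over all genes, the complex I subunit Ndufs5, which fell by 0.29 (SE 0.05, limma adjusted p = 0.049). Adjusted over the list alone, 1 gene of complex I, Ndufs5, passed, 1 of complex III and 0 of the others. Ndufs5 lost its call whichever array was left out (adjusted p up to 0.128).

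**Figure D1:**
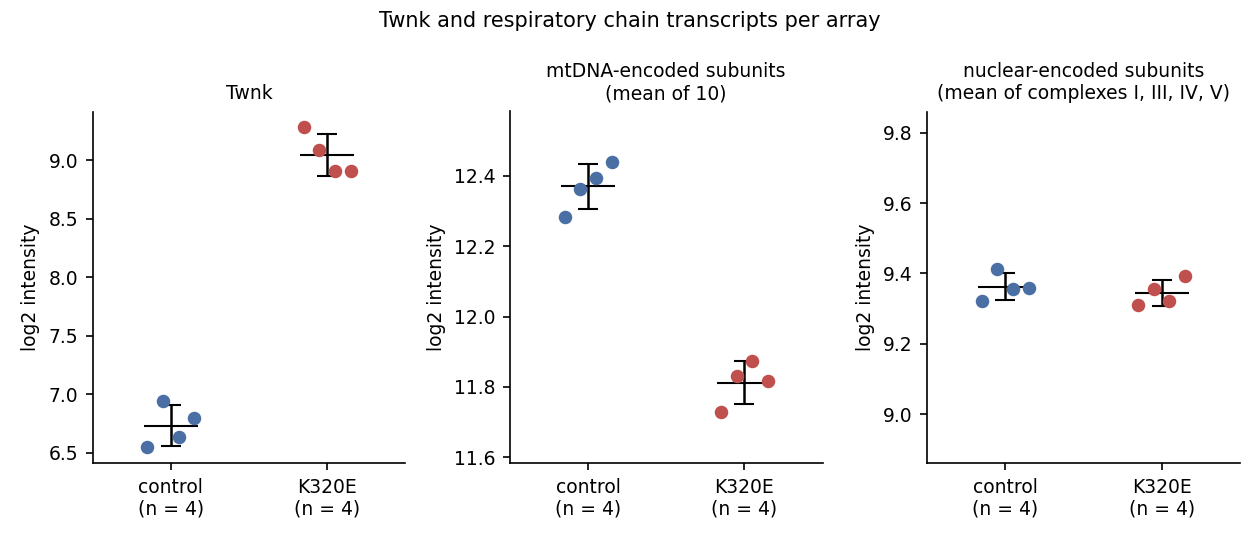
Log2 intensity of Twnk, mean of the 10 measured mtDNA-encoded subunits and mean of the nuclear-encoded subunits of complexes I, III, IV and V, with 1 point per array, the group mean as a line and the SD as bars; the axes do not start at 0, and the middle and right axes both span 1 log2 unit. The K320E arrays lie above the controls for Twnk (9.05 against 6.73) and below them for the mtDNA-encoded mean (11.81 against 12.37), and the groups overlap for the nuclear-encoded mean (9.34 against 9.36).

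Other lists of mitochondrial function moved little. Twnk itself was not among the measured members of the mtDNA maintenance and transcription list. Genes of mtDNA maintenance and transcription (18 genes, median -0.06, camera adjusted p = 0.2), the mitochondrial ribosome (70 genes, median 0.03, camera adjusted p = 0.336) and mitochondrial fatty acid oxidation (16 genes, median 0.06, camera adjusted p = 0.509) had no camera call, and 0 of their members passed limma's test over all genes or adjusted over the list alone. Mitochondrial chaperones and proteases shifted upward (17 genes, median 0.12, camera adjusted p = 0.0076; adjusted p = 0.325 with an estimated correlation), with 0 genes past the threshold and 3 adjusted over the list alone. The citric acid cycle list did so too (16 genes, median 0.12, camera adjusted p = 0.008; adjusted p = 0.325 with an estimated correlation), with 0 genes past the threshold and 5 adjusted over the list alone. Without control replicate 4 the median of the citric acid cycle list was 0.07.

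Genes of the integrated stress response, the programme driven by the transcription factor ATF4, rose together. Of the 32 measured members, 15 rose and 0 fell over all genes, 26 rose when adjusted over the list alone, and all 32 fold changes were positive (limma). The largest increases were in Mthfd2, a mitochondrial enzyme of one-carbon metabolism, by 1.59 (SE 0.14, limma adjusted p = 0.0028), in Cth, which makes cysteine from cystathionine, by 1.46 (SE 0.15, limma adjusted p = 0.0057), and in the cystine transporter Slc7a11 by 1.29 (SE 0.17, limma adjusted p = 0.013). The asparagine synthetase gene Asns rose by 0.99, and Ddit3, which encodes CHOP, by 0.38. Fgf21, a secreted factor of this programme, had a fold change of 0.05, and Atf4 itself one of 0.33, neither past the threshold. The list had a median of 0.55 (camera adjusted p = 4.14e-28; adjusted p = 0.0375 with an estimated correlation). Slc7a11 lost its call without K320E replicate 3 (adjusted p = 0.051), while Mthfd2 and Cth passed the threshold whichever array was left out.

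**Figure D2:**
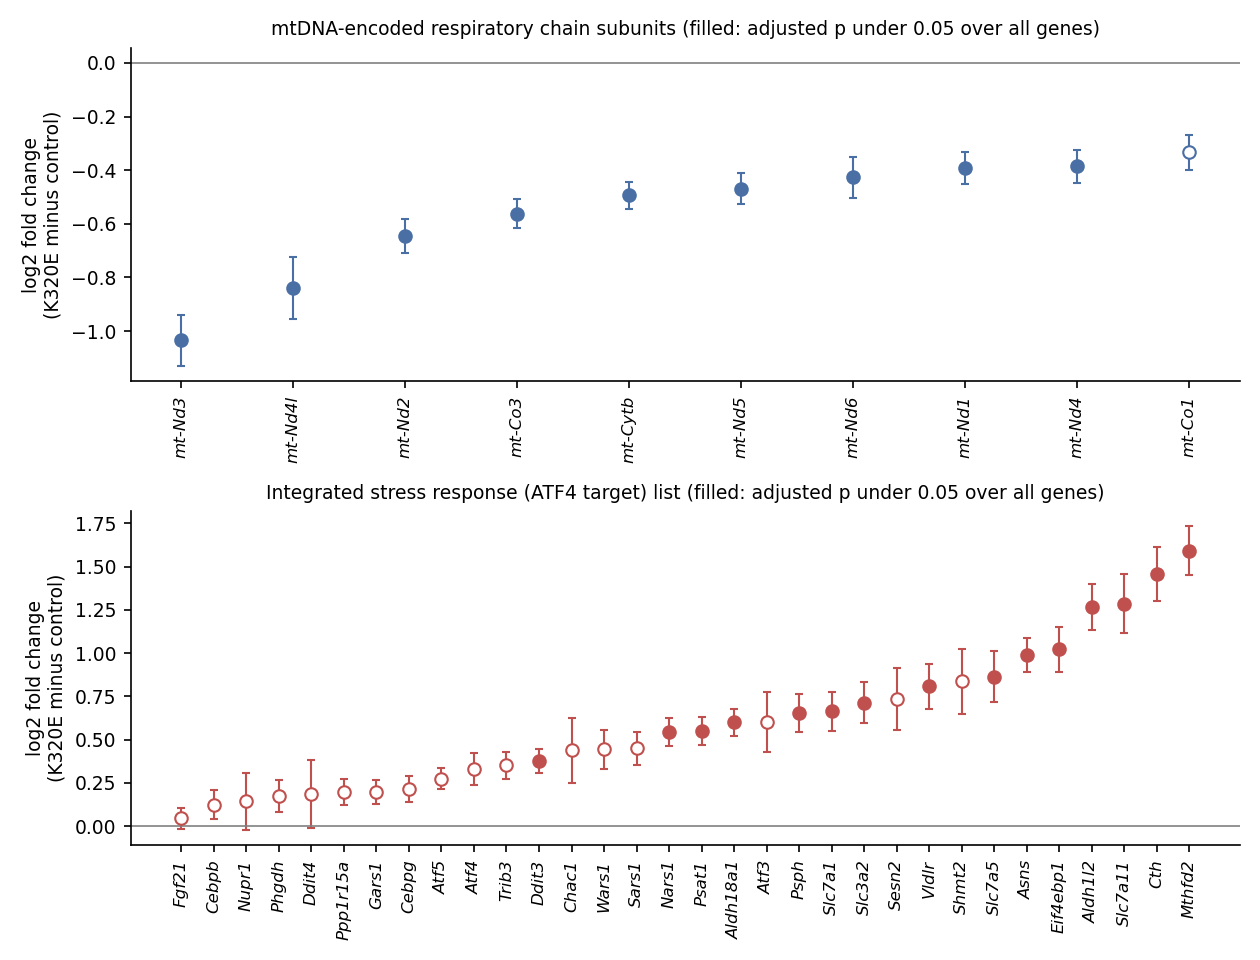
Log2 fold change (K320E minus control, 4 arrays each) of every measured member of the mtDNA-encoded list and of the integrated stress response list, 1 point per gene with its SE as bars; filled points have a limma adjusted p under 0.05 over all genes. All 10 mtDNA-encoded subunits lie below 0 and 9 are filled, and all 32 stress response genes lie above 0 and 15 are filled.

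Over all genes, 195 of 22180 differed between the genotypes (limma adjusted p under 0.05): 152 were higher in K320E and 43 lower. At least a 2-fold change was seen for 37 of the higher and 5 of the lower genes. Among the called genes, the strongest increases were in Epgn, an EGF-family growth factor, by 2.76 (SE 0.18), the pseudogene Sprr2j-ps by 2.54 (SE 0.34), Ptgs2, the inducible cyclooxygenase, by 2.45 (SE 0.27), and Slpi, a secreted protease inhibitor, by 2.43 (SE 0.33). The lowest fold changes among them were in the hair keratin-associated gene Krtap21-1, which fell by 2.67 (SE 0.49), the cytochrome P450 gene Cyp2g1, which fell by 1.94 (SE 0.26), and the steroid dehydrogenase gene Hsd3b6, which fell by 1.79 (SE 0.25). Clca3a2 fell by 0.87 (SE 0.11). All 195 called genes had groups that did not overlap; among all genes this held for 2052, or 9.25%, where chance gives 2.86%. At an unadjusted p under 0.05 there were 3288 genes. Of the 45 fixed lists, camera called 23, 18 shifted up and 5 down, and 4 of the 35 splits of the arrays into 4 and 4, the real one included, gave at least as many. Among them were markers of other cells: skeletal muscle (median 0.32) and mast cells (0.14) up, and sebocytes (-0.38), melanocytes (-0.24) and Langerhans and dendritic cells (-0.05) down. With an estimated correlation 1 of the 23 calls was kept, and all 5 of these cell type calls were lost (adjusted p = 0.118 to 0.458). Fewer genes were called without control replicate 1 (87), control replicate 2 (87), control replicate 4 (118), K320E replicate 1 (105), K320E replicate 3 (53) or K320E replicate 4 (77). Without those arrays in turn, the named genes past the threshold went from 35, Twnk apart, to between 14 and 28, while over all 8 reduced fits their fold changes stayed within 0.79 to 1.17 times the full ones. Krtap21-1 passed in 2 of the 8 reduced fits, Hsd3b6 in 5, Sprr2j-ps in 6 and Cyp2g1 in 7.

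Genes of the cornified envelope that keratinocytes raise when stressed were higher in K320E. In the list of small proline-rich and LCE3 proteins, 9 of 17 genes rose over all genes and 14 adjusted over the list alone, and 0 fell. Lce3d rose by 2.22 (SE 0.18, limma adjusted p = 0.0021) and Sprr1b by 2.14 (SE 0.29, limma adjusted p = 0.013). Sprr2g, which the gene table names a transcribed pseudogene, rose by 2.04 (SE 0.32, limma adjusted p = 0.025). The list had a median of 1.38 (camera adjusted p = 3.84e-16; adjusted p = 0.118 with an estimated correlation). Hair structure genes moved the opposite way in these arrays (median -0.77), and control replicate 4, the lowest array for this list (mean 7.47), was the highest for theirs (8.64). The stress keratins had 0 of 4 genes past the threshold and 3 adjusted over the list alone (median 1.24, camera adjusted p = 0.0015; adjusted p = 0.325 with an estimated correlation). Krt6a had a fold change of 1.80 and Krt16 of 1.02. Without control replicate 4 the median of the stress keratins was 0.72. With the level of the hair structure list as a covariate it was 0.25, and the call ended (camera adjusted p = 0.226). Paralogs of the Sprr2 family share sequence, so the values of its single members are uncertain. Sprr2g passed in 3 of the 8 reduced fits and Sprr1b in 6, the highest adjusted p being 0.081 and 0.057.

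Growth factors of the EGF family rose as well: 4 of 7 over all genes, namely Epgn, Nrg1, Hbegf and Tgfa, and 5 adjusted over the list alone. Nrg1 rose by 2.19 (SE 0.19, limma adjusted p = 0.0028) and Hbegf by 0.94 (SE 0.17, limma adjusted p = 0.049), while Tgfa, which the naming rule does not take and which was chosen after its value was seen, rose by 0.51. The list had a median of 0.80 (camera adjusted p = 9.82e-07; adjusted p = 0.118 with an estimated correlation). Among wound proteases and matrix genes, 2 of 14 rose over all genes and 9 adjusted over the list alone (median 0.56, camera adjusted p = 9.14e-09; adjusted p = 0.118 with an estimated correlation). These were the membrane protease Adam8, by 0.97 (SE 0.14), and the fibronectin receptor subunit Itga5, by 0.56 (SE 0.08). With the level of the hair structure list as a covariate, the medians were 0.51 for the EGF family and 0.28 for wound proteases and matrix, both still called. Hbegf passed in 1 of the 8 reduced fits, Adam8 in 3 and Itga5 in 7 (adjusted p up to 0.147, 0.069 and 0.061).

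Alarmins, antimicrobial peptides and cytokines showed rises in a few members. Of 20 alarmins and antimicrobial peptides, 2 rose over all genes: Slpi, and the peptidoglycan-binding gene Pglyrp3 by 0.71 (SE 0.09, limma adjusted p = 0.013). Adjusted over the list alone, 10 rose and 1 fell (median 0.32, camera adjusted p = 5.62e-06; adjusted p = 0.118 with an estimated correlation). S100a8 and S100a9 had fold changes of 1.73 and 1.56, with adjusted p of 0.074 and 0.070 in limma. Neutrophils carry both, and 11 of 12 neutrophil markers had positive fold changes (median 0.06, camera adjusted p = 0.055; adjusted p = 0.033 by fry). With the level of the hair structure list as a covariate, the alarmin median was 0.17, still called. Of 39 cytokines and chemokines, 2 rose over all genes and 3 adjusted over the list alone: Il24 by 1.41 (SE 0.16, limma adjusted p = 0.0066) and the epithelial alarmin Il33 by 1.04 (SE 0.18, limma adjusted p = 0.04) were those over all genes. Mast cell markers moved the same way (median 0.14), as did those of skeletal muscle (0.32). The cytokine list had a median of 0.07 (camera adjusted p = 0.043; adjusted p = 0.445 with an estimated correlation). Its call was lost without control replicate 1 (adjusted p = 0.081), control replicate 4 (adjusted p = 0.207, median 0.04), K320E replicate 1 (adjusted p = 0.135) or K320E replicate 4 (adjusted p = 0.121). Slpi lost its call without K320E replicate 3 or 4 (adjusted p up to 0.063), Pglyrp3 without K320E replicate 3 (0.051), and Il33 passed in 1 of the 8 reduced fits.

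Interferon-stimulated genes were not shifted (20 genes, camera adjusted p = 0.391), with a median of 0.03 and a mean of -0.03 that differ in sign, the test pointing down; 0 members passed over all genes or adjusted over the list alone.

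**Figure D3:**
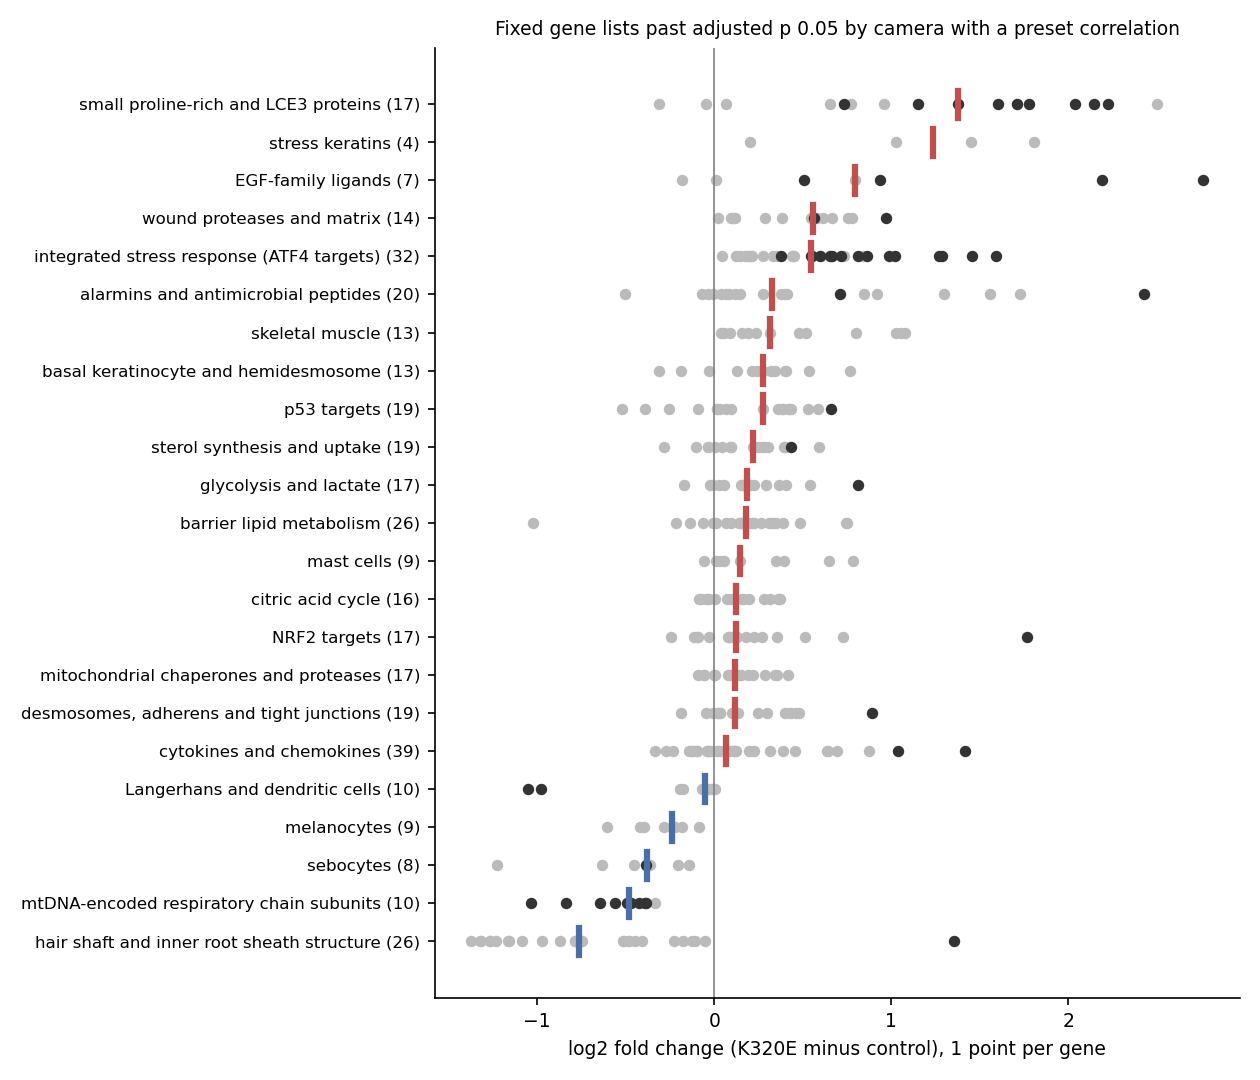
Log2 fold change (K320E minus control, 4 arrays each) of each measured gene in the 23 lists with a camera adjusted p under 0.05 at the preset correlation, with the number of genes in brackets; dark points have a limma adjusted p under 0.05 over all genes, and the thick line is the list's median, red where camera's direction was up and blue where it was down. The medians run from -0.77 for the hair shaft and inner root sheath list to 1.38 for the small proline-rich and LCE3 list; 1 of the 23 calls, that of the integrated stress response, holds with an estimated correlation.

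Keratinocyte adhesion genes shifted upward by smaller amounts. Of 19 genes of desmosomes, adherens and tight junctions, 1 rose over all genes, the desmosomal cadherin Dsg3, by 0.89 (SE 0.11, limma adjusted p = 0.013), and 5 adjusted over the list alone (median 0.12, camera adjusted p = 0.00021; adjusted p = 0.244 with an estimated correlation). The basal keratinocyte and hemidesmosome list had 0 of 13 genes past the threshold; 6 rose and 1 fell adjusted over the list alone (median 0.27, camera adjusted p = 0.0005; adjusted p = 0.325 with an estimated correlation). Late differentiation and cornified envelope genes (28 genes, 0 past the threshold, 3 adjusted over the list alone, median 0.08, camera adjusted p = 0.072) and spinous keratinocyte genes (14 genes, 0 past the threshold, 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.204) had no call, nor had the cell cycle list (33 genes, 0 past the threshold, 0 adjusted over the list alone, median 0.11, camera adjusted p = 0.192). The late differentiation list gained a call without control replicate 2 (median 0.14, adjusted p = 0.0022), control replicate 3 (0.12, 0.0069), K320E replicate 3 (0.11, 0.030) or K320E replicate 4 (0.09, 0.027). Its median was 0.04 without control replicate 1 and 0.05 without control replicate 4. With the level of the hair structure list as a covariate, camera called the late differentiation list downward (median -0.0898, adjusted p = 0.0463). It was called under 3 of the 12 alternatives other than leaving out each array, this covariate included. The other calls pointed up. Over the 12 the median ran from -0.09 to 0.23, with a lowest camera adjusted p of 9.81e-07. The cell cycle list gained a call without control replicate 1 (median 0.13, adjusted p = 0.0063), and over the 8 reduced fits its median ran from 0.03 to 0.13. It was also called under 1 of the 12 other alternatives (camera adjusted p = 0.0057). Dsg3 lost its call without K320E replicate 3 (adjusted p = 0.051).

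Metabolic and stress lists shifted upward, with 0 or 1 gene called in each. Hexokinase Hk2 was the 1 called gene of 17 in glycolysis and lactate, rising by 0.81 (SE 0.14, limma adjusted p = 0.036), with 2 adjusted over the list alone (median 0.18, camera adjusted p = 0.00064; adjusted p = 0.325 with an estimated correlation). The glutathione transferase Gsta4 was the 1 called gene of 17 NRF2 targets, rising by 1.77 (SE 0.18, limma adjusted p = 0.0043), with 2 adjusted over the list alone (median 0.12, camera adjusted p = 0.015; adjusted p = 0.339 with an estimated correlation). The kinase Plk2 was the 1 called gene of 19 p53 targets, rising by 0.66 (SE 0.06, limma adjusted p = 0.0037); 10 rose and 2 fell adjusted over the list alone (median 0.27, camera adjusted p = 0.00074; adjusted p = 0.118 with an estimated correlation). Squalene epoxidase Sqle was the 1 called gene of 19 in sterol synthesis and uptake, rising by 0.43 (SE 0.08, limma adjusted p = 0.0495), with 6 adjusted over the list alone (median 0.22, camera adjusted p = 0.00074; adjusted p = 0.445 with an estimated correlation). Barrier lipid metabolism had 0 of 26 genes past the threshold; 3 rose and 1 fell adjusted over the list alone (median 0.18, camera adjusted p = 0.00074; adjusted p = 0.546 with an estimated correlation). Without K320E replicate 1 the medians were 0.10 for glycolysis, 0.08 for sterol synthesis, 0.09 for barrier lipids and 0.08 for NRF2 targets, whose call ended (adjusted p = 0.070). The NRF2 median was 0.08 also without control replicate 1 or 4. With the level of the hair structure list as a covariate, the barrier lipid median was 0.0237, with no call and camera pointing down (adjusted p = 0.888). Sqle lost its call whichever array was left out (adjusted p up to 0.115), and Hk2 passed in 2 of the 8 reduced fits.

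Structural genes of the hair shaft and inner root sheath were lower in K320E as a group. Of 26 genes, 25 had negative fold changes, with a median of -0.77 (camera adjusted p = 2.78e-09; adjusted p = 0.325 with an estimated correlation). Over all genes 0 fell and 1 rose, and adjusted over the list alone 6 fell and 1 rose (limma). Tchh, which encodes trichohyalin of the inner root sheath, had a fold change of -1.32 (SE 0.30) and Krt71, an inner root sheath keratin, one of -1.37 (SE 0.36), neither past the threshold. The gene that rose was Dsc2, by 1.35 (SE 0.22, limma adjusted p = 0.027), a desmosomal cadherin that epidermis outside the follicle also expresses. The list mean was 7.26 ± 0.18 in K320E and 7.93 ± 0.56 in controls (SD, n = 4 each, exact permutation p = 0.0571). The groups overlapped, since control replicate 2 (7.43) lay below K320E replicate 4 (7.46). By contrast, the 22 genes of hair follicle signalling, among them Shh (-0.01) and Lhx2 (0.14), had a median of 0.01 (camera adjusted p = 0.768), with 0 past the threshold over all genes or adjusted over the list alone. Without control replicate 4 the median of the structural list was -0.46, and Dsc2 passed in 1 of the 8 reduced fits (adjusted p up to 0.081).

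Markers of melanocytes and sebocytes, cells that sit in and beside the follicle, moved with the hair list. Of 9 melanocyte genes 0 fell over all genes or adjusted over the list alone, all 9 fold changes were negative, and the median was -0.24 (camera adjusted p = 0.00058; adjusted p = 0.339 with an estimated correlation). Mlana and Dct, the most highly expressed of them, had fold changes of -0.40 and -0.29. Of 8 sebocyte genes, 1 fell over all genes, Far2, a fatty acyl reductase, by 0.39 (SE 0.06, limma adjusted p = 0.025), and 2 adjusted over the list alone (median -0.38, camera adjusted p = 0.00021; adjusted p = 0.118 with an estimated correlation). Control replicate 4 was apart in this list (mean 7.85, other controls 7.10 to 7.13), and without it the median was -0.26 and the difference of the list means went from -0.47 to -0.29. Mgst1 had a fold change of -0.21, and of -0.08 without control replicate 4 and -0.31 without K320E replicate 3. That of Dct was -0.18 without control replicate 1. Far2 passed in 2 of the 8 reduced fits (adjusted p up to 0.092).

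**Figure D4:**
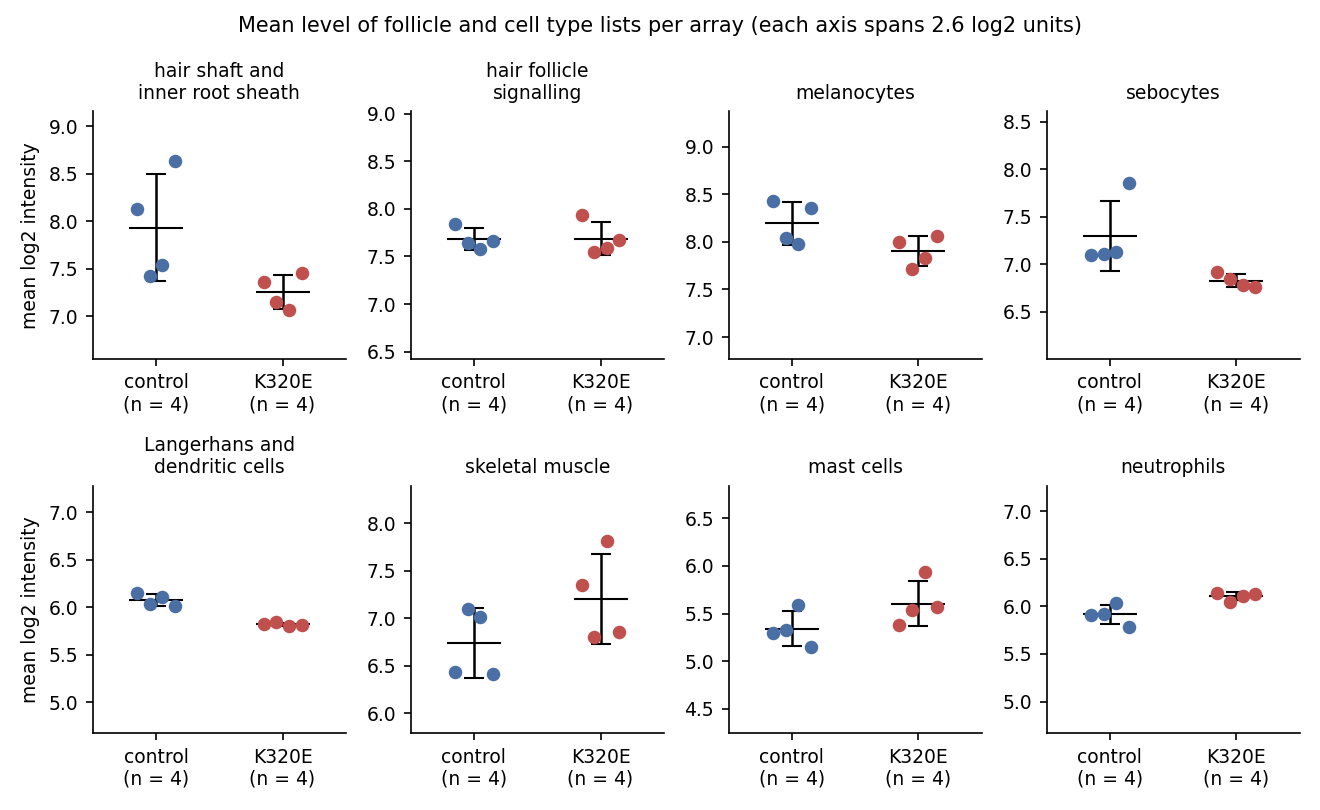
Mean log2 intensity of follicle and cell type lists, with 1 point per array, the group mean as a line and the SD as bars (4 arrays per group); the axes do not start at 0 and each spans 2.6 log2 units. The control arrays spread widely for the hair shaft and inner root sheath list (7.93 ± 0.56, SD). The groups overlap there, with control replicate 2 (7.43) below K320E replicate 4 (7.46), and also for hair follicle signalling (mean difference 0.007).

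Genes of MHC class II chains fell. In the list of Langerhans and dendritic cells, 2 of 10 genes fell over all genes and adjusted over the list alone: H2-Aa fell by 1.05 (SE 0.08, limma adjusted p = 0.0021) and H2-Ab1 by 0.98 (SE 0.13, limma adjusted p = 0.013). The other 8 genes did not pass, with fold changes from -0.19 to 0.00, among them Cd207, the Langerhans cell lectin (-0.07), and Ciita, the class II transactivator (0.00), so that the list had a median of -0.05 and a mean of -0.26 (camera adjusted p = 0.00074; adjusted p = 0.118 with an estimated correlation). H2-Ab1 lost its call without K320E replicate 3 (adjusted p = 0.051), and the list's median was -0.03 without control replicate 1.

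Of the other immune cell lists, neutrophil genes had no camera call (12 genes, 11 of them positive, median 0.06, mean 0.19, adjusted p = 0.055), with 0 members past the threshold or adjusted over the list alone. Their mean was 6.11 ± 0.04 in K320E and 5.92 ± 0.10 in controls (SD, n = 4 each; exact permutation p = 0.0286, or 0.080 adjusted over the 45 lists), and fry called the list (adjusted p = 0.033). Camera called it without control replicate 1 (median 0.10, adjusted p = 0.049), control replicate 3 (median 0.09, adjusted p = 0.019) or K320E replicate 2 (median 0.09, adjusted p = 0.043), and under 3 of the other alternatives. Cxcr2 had a fold change of 1.32 and Stfa2l1 of 0.05 (-0.05 to 0.15 when each array was left out). The monocyte and macrophage list (14 genes, camera adjusted p = 0.839) had a median of -0.07 and a mean of 0.006, which differ in sign, with the test pointing down. Of its members, 0 passed over all genes and 2 adjusted over the list alone, and Cd68 and C1qb had fold changes of 0.51 and -0.13. That of C1qb was -0.27 without control replicate 1, -0.04 without control replicate 3, -0.07 without control replicate 4 and -0.08 without K320E replicate 4. In the T cell and pan-leukocyte list (8 genes, median -0.31, camera adjusted p = 0.189), Thy1 rose by 0.69 (SE 0.13, limma adjusted p = 0.0495) as the 1 called gene, 2 rose and 4 fell adjusted over the list alone, and Ptprc had a fold change of -0.54. The T cell list was called without K320E replicate 2 (median -0.44, adjusted p = 0.016). Thy1 is also expressed by fibroblasts and nerves, and it passed in 1 of the 8 reduced fits (adjusted p up to 0.146). Mast cell genes shifted upward (9 genes, 0 past the threshold, 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.046; adjusted p = 0.441 with an estimated correlation), with fold changes of 0.65 for Cpa3 and 0.78 for Hdc. The mast cell call was lost without any 1 array other than control replicate 3 or K320E replicate 1 (adjusted p from 0.085 to 0.119), and without K320E replicate 1 its median was 0.22. The fold change of Cpa3 was 0.12 without K320E replicate 3 and 0.99 without K320E replicate 1.

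Markers of the remaining cell types, most of them from tissue below the epidermis, varied between arrays. Skeletal muscle genes shifted upward in K320E, with 0 of 13 past the threshold or adjusted over the list alone (median 0.32, camera adjusted p = 0.0024; adjusted p = 0.458 with an estimated correlation). Tnnt3 and Mylpf had fold changes of 1.03 and 1.08. K320E replicate 3 was highest in this list, at a mean of 7.81, and without it the median was 0.20 and the call ended (adjusted p = 0.087). The median was 0.20 also without control replicate 1. Fibroblast (15 genes, median 0.15, camera adjusted p = 0.114), endothelial (12 genes, median 0.02, camera adjusted p = 0.565), adipocyte (9 genes, median 0.17, camera adjusted p = 0.189), erythroid (3 genes, median -0.07, camera adjusted p = 0.391) and Merkel cell (7 genes, median 0.06, camera adjusted p = 0.727) lists had no call. Schwann cell genes had none either (7 genes, camera adjusted p = 0.732), with a median of -0.04 and a mean of 0.06 that differ in sign, the test pointing up. In these 6 lists 0 genes passed over all genes or adjusted over the list alone. Among their most highly expressed members the fold changes were -0.23 for Postn, -0.14 for Dcn, 0.38 for Lyve1, 0.10 for Cdh5, 1.24 for Fabp4, 1.44 for Car3, 0.01 for Slc4a1, -0.10 for Hemgn, -0.15 for Erbb3, 0.21 for Mbp, 0.06 for Krt18 and 0.22 for Krt8. K320E replicate 3 was highest in the adipocyte list too (mean 8.19), and without it the fold changes were 0.53 for Car3, 0.77 for Fabp4, 0.19 for Lyve1, -0.17 for Cdh5, 0.65 for Tnnt3 and 0.71 for Mylpf. Other fold changes that 1 array moved by over 1.5 times were Dcn (-0.09 without control replicate 1, -0.26 without control replicate 4), Erbb3 (-0.09 without control replicate 3, -0.28 without K320E replicate 1, -0.05 without K320E replicate 4), Hemgn (-0.05 without control replicate 1) and Krt8 (0.14 without control replicate 4). Over the 8 reduced fits Slc4a1 ran from -0.08 to 0.06, Krt18 from -0.01 to 0.11 and Cdh5 from -0.17 to 0.20. The fibroblast list was called without control replicate 3 (median 0.21, adjusted p = 0.0099) or K320E replicate 1 (median 0.16, adjusted p = 0.039). Of the 12 alternatives other than leaving out each array, 2 also called it (lowest camera adjusted p = 0.0016), with medians from -0.002 to 0.29 over the 12. The erythroid list was called under 1 of them (camera adjusted p = 0.031). The adipocyte list was called without K320E replicate 1 (median 0.26, adjusted p = 0.041). The adipocyte median was 0.02 without K320E replicate 3.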

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

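All tests of explanations in this part were chosen or worded after the result was seen.

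The 195 called genes were set against other groupings of the arrays. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave at least 195 genes. The highest of the other splits gave 0. Every other split mixes the genotypes, so a genotype difference widens the spread within its groups and lowers its count. With 1 of 35 the smallest share possible, the splits cannot exclude chance for the gene count. Nor can they for the count of fixed lists. There the real split gave 23 lists, and the highest of the other splits gave 29. In 4 of the 35 splits, the real one included, at least 23 were called. The 3 others each kept 3 K320E arrays together and exchanged 1 of them for a control, control replicate 3 in 2 cases and control replicate 2 in 1.

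The lower mtDNA-encoded transcripts (median -0.48) were set against 2 other readings. A general fall of bright probe sets is argued against by 10000 random lists matched on level, of which 0% had a median as low. Their medians ran from -0.20 to 0.21. The genes of the random lists were drawn independently. Those of the mtDNA-encoded list had an estimated correlation of 0.446, so the 0% may overstate how far it stood apart. A fall of all respiratory chain transcripts is argued against by the nuclear-encoded mean, which differed by -0.0175 with a 95% interval from -0.083 to 0.048. What stays open is whether K320E lowers the template, its transcription or the stability of the transcripts, since mtDNA itself was not analysed here. Whether the bright probe sets understate the change was not tested. An effect of the genotype, the difference that the design names, stays among the open explanations and was not tested apart from this comparison.

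The lower hair structure genes (median -0.77) came with lower melanocyte and sebocyte lists. Fewer follicles as the sole cause could not be settled: the hair follicle signalling mean differed by 0.00666 (95% interval from -0.246 to 0.259), and the structural minus the signalling mean by -0.681 (95% interval from -1.35 to -0.011; exact permutation p = 0.0286), but by -0.440 with p = 0.0571 without control replicate 4. Nor could control replicate 4 as the sole source: without it the median was -0.455 (camera adjusted p = 8.12e-08), between the bounds set for either reading. A difference in hours of age, in how far follicles had matured or in how deep the epidermis was separated stays open and was not tested. A biological effect of the genotype on hair shaft formation stays among these open explanations.

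In 12 of 170 tests of a group of 4 arrays, 1 array lay far from the other 3, where chance gives about 1 in 20; the 12 cases fell on 5 arrays. Control replicate 4 was apart in Cyp2g1 (11.1 against 9.84 to 9.96), in Cth (6.49 against 6.70 to 6.74), in the mean of the small proline-rich and LCE3 list (7.47 against 8.15 to 8.28) and in the mean of the sebocyte list (7.85 against 7.10 to 7.13). K320E replicate 1 was apart in Adam8 (7.45 against 7.13 to 7.17), in the sterol synthesis list (9.34 against 8.98 to 9.01) and in the desmosome and junction list (9.93 against 9.72 to 9.75). K320E replicate 2 was apart in Gsta4 (9.10 against 9.68 to 9.77) and in the mitochondrial chaperone list (8.95 against 9.04 to 9.05). K320E replicate 3 was apart in Cdh5 (7.40 against 6.29 to 6.30) and Mgst1 (8.05 against 7.62 to 7.64), and K320E replicate 4 in Postn (11.5 against 11.28 to 11.29).

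Outside the genes compared, 32 of the 10272 probe sets without a single gene name passed limma's adjusted p over all probe sets, 11 of them higher and 21 lower in K320E.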

How the results depend on the processing

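Leaving out control replicates 2 and 3 together and the covariate for the hair structure list were chosen after the data were seen; the other alternatives were planned. The Twnk difference kept its direction and its side of the threshold under all alternatives run, with log2 fold changes from 2.23 to 2.38 when each array was left out. The count of 195 genes became 111 with a minimum fold of 1.5, which only removes genes, and 15 with the hair structure list as a covariate (13 of them among the 195). That covariate differs between the genotypes, and it widened the SE of the called genes by a median of 1.39 times while their fold changes had a median of 0.91 times the original, all 195 in the same direction; for mt-Nd3 the log2 fold change was -1.04 (SE 0.10) before and -1.06 (SE 0.14) after. Leaving out each array gave 53 to 173 genes. There were 87 without control replicate 1, 87 without control replicate 2 and 118 without control replicate 4. There were 105 without K320E replicate 1, 53 without K320E replicate 3 and 77 without K320E replicate 4. Fewer samples can lower the count, but the cause of these counts and of the difference between arrays was not tested. Without control replicates 2 and 3 there were 185 genes, of which 89 were among the 195. Of the 9 other alternatives, the replicate number as a block gave 114 genes and the other 8 between 133 (Y-linked covariate) and 288 genes (dim genes left out).

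The count of 23 lists became 1 with an estimated correlation, 11 by fry, which tests a list without comparing it with other genes, and 14 with the hair structure covariate; leaving out each array gave 21 to 26. That covariate ended 11 of the 23 calls: those of the hair structure list itself, melanocytes, sebocytes, stress keratins, barrier lipids, the citric acid cycle, cytokines, mast cells, mitochondrial chaperones, NRF2 targets and skeletal muscle. Of the 12 it kept, it moved 4 medians by over 1.5 times: alarmins from 0.325 to 0.169, EGF-family ligands from 0.796 to 0.514, wound proteases and matrix from 0.556 to 0.281, and Langerhans and dendritic cells from -0.0535 to -0.0912. With it the median of the barrier lipid list was 0.0237 and that of the late differentiation list -0.0898 (camera adjusted p = 0.888 and 0.0463), against 0.179 and 0.0789 in the full fit, and camera's direction was turned to down for both; the cause was not tested. Among the named genes other than Twnk, leaving out each array moved 87 results out of the calls and 1 into them, and the other alternatives 67 and 2; for single lists these counts were 12 and 12, and 51 and 12, the 2 lists whose direction turned included. The mtDNA-encoded minus nuclear-encoded difference ran from -0.57 to -0.52 when each array was left out. Without control replicates 2 and 3 it was -0.553, with an exact permutation p of 0.0667, the smallest that 4 arrays against 2 allow. It has no covariate, weight or trend term and was not run under those. The values are on the log2 scale, so the alternative planned for linear values does not apply.

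It is not known whether the replicate numbers pair the arrays. The correlations of same-numbered deviations were 0.05, -0.06, 0.08 and 0.14, and 4 of 8 arrays correlated best with their own number. These values neither show nor exclude a pairing. With the replicate number as a block, 114 genes passed, 89 of them among the 195, and 24 lists; the mtDNA-encoded minus nuclear-encoded difference stayed at -0.541, with a p of 0.125, the smallest an exact test of 4 pairs allows. Signal over background could not be judged, since background levels were not used here.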

Other observations

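The tests and gene groups in this part were chosen after the data were seen; the gene groups were picked from these values, so no test of a group is given.

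Genes outside the fixed lists also rose in K320E. Of 14 cytosolic aminoacyl-tRNA synthetases that are not in the stress response list, which charge tRNAs with amino acids, 3 rose over all genes: Cars by 0.56, Yars by 0.52 and Mars1 by 0.46. Of 32 nucleolar factors of ribosome assembly, 3 rose, Nop2 by 0.55, Bysl by 0.47 and Pdcd11 by 0.33. Of 7 genes of polyamine metabolism, 3 rose, and Oaz1 and Oaz2 had fold changes of -0.33 and -0.08; those that rose were the synthesis enzymes Odc1 by 0.71 and Srm by 0.82 and the spermine oxidase Smox by 0.84. The epidermal connexins Gjb2 and Gjb6 rose by 0.78 and 0.66, the dual oxidase Duox1 and its maturation factor Duoxa1 by 0.95 and 1.07, and the transcription factors Hif1a and Nfe2l2 (NRF2) by 0.73 and 0.49, while Cox20, an assembly factor of complex IV, fell by 0.49.

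Of 51 keratin-associated protein genes, 49 had negative fold changes and 1 fell, Krtap21-1. Their mean was 7.90 in control replicate 4 and between 6.27 and 6.61 in the other controls. All 11 Skint genes, which keratinocytes and thymic epithelium express, had negative fold changes, with 0 past the threshold.

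Sex-linked transcripts placed 2 control arrays apart. Xist lay between 12.1 and 12.3 in 5 arrays, which had low Y-linked means (4.75 to 4.82), and at 6.84 in K320E replicate 3, whose Y-linked mean was 8.64. Control replicate 3 was low in both, with Xist at 6.17; a single X chromosome without a Y could not be told apart from other readings, since 3 of 9 genes known to escape X inactivation lay below all 5 arrays high in Xist, and the Y-positive arrays showed no more (2 and 3 of 9). Control replicate 2 had Y-linked genes at 9.05 and Xist at 9.27, or 13.3% of the mean of the 5 arrays; a mixture of RNA from an XX and an XY pup remains a candidate explanation that these values do not settle, and the labels give no sex. The design names no biological difference within the controls, and no explanation beyond these 2 was tested.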
